A study of Sinorhizobium meliloti with 16 samples.

How the data were processed

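RNA sequencing of Sinorhizobium meliloti Rm1021 (WT) and of a strain with the disordered region of RNase E deleted (rneΔIDR) was analysed from 16 deposited tables, one per library, with 2 biological replicates per strain and time. Cultures grew in TY medium at 28 °C to an OD600 between 0.3 and 0.5 and received 200 µg/mL rifampicin, per the labels' protocols. Samples went directly into an RNA stabilising reagent at 0, 1, 3 and 9 min, the first of them before the drug. Libraries were made from 5 µg of total RNA by ligation of an adenylated DNA oligonucleotide, reverse transcription, circularisation and PCR, per the labels' protocols. Bowtie 0.12.8 is named in the submitters' processing notes. The counting tool, the genome build, the annotation, and whether strand was used in counting are not given in the sources used here, so reads of overlapping or antisense genes and of repeated sequences could not be told apart.

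Each deposited table gave read counts per locus tag as whole numbers, per the file headers, which were not normalised by the authors. Each also gave the authors' RPKM. Every RPKM equalled the count over a length and a library total, where the total is the other deposited number, a single value in the last line of each table that names no gene. That line was kept out of the tests. The lengths came out as whole numbers within 2.59e-08 for 6167 loci, and with both end positions counted 6166 were multiples of 3, so they are coding lengths without untranslated regions. Reads in genes were 12.4% to 22.7% of the deposited totals, and the remaining 77.3% to 87.6% lay outside the listed genes. What RNA those reads came from is not given in the sources used here. RPKM values are therefore relative to a total dominated by reads outside coding genes. No spike-in was analysed here.

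Loci are identified by locus tag only. Of the 6234 tags, 0 matched the reference gene table supplied, which belongs to an assembly of another strain with 6299 genes, so no gene names or products are given, and lists of genes fixed before the data were examined could be tested only where they rest on the tag prefix (chromosome SMc, pSymA SMa, pSymB SM_b). Lists by gene name, product or type of RNA were not analysed here, nor was the rne transcript, so the deletion was not checked in these libraries.

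Per-locus tests used the read counts with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests (glmQLFit and glmQLFTest) with 1 mean for each of the 8 groups over all 16 libraries, so that groups of 2 shared the estimate of the spread. A test on log2(RPKM + 1) with limma 3.58.1 had been planned for tables without counts, with edgeR in its place where counts were found. Loci with a mean RPKM of 5 or more over the 16 libraries were tested (4171, with 2846 on the chromosome, 533 on pSymA and 791 on pSymB). The design fixed column totals without further scaling as library sizes before the data were examined. Once the files showed both gene reads and a deposited total, this was read as the sum of gene reads, although the wording also allows the deposited totals, and the choice moves the count of slope differences from 38 to 308. Slopes are contrasts of the 4 group means with least-squares weights on time, in log2 units per min, and the strain difference is the rneΔIDR slope minus the WT slope. Calls are at a Benjamini-Hochberg adjusted p below 0.05 within each contrast. Slopes relative to gene reads omit the part of the decay that all gene reads share, so the same fit with the deposited totals as library sizes was added after the data were examined. Its counts stand beside the others. Pseudocounts, filters, scalings (TMM, DESeq2 size factors, library medians), DESeq2 1.42.0, time windows, blocks, and the leaving out of each library and each culture were alternatives.

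Median half-lives came from the deposited RPKM. For each locus and culture, log2(RPKM + 1) was fitted on time by least squares, the half-life was -1/slope where the slope was below 0, and the median was taken over the falling tested loci. Values of 2 against 2 cultures were compared by an exact two-sided permutation test. The replicon lists were tested with camera at a preset correlation of 0.01, with the estimated correlation beside it, and with fry as an alternative. By the rule fixed beforehand, at most 2 loci without a gene name per direction are named for a comparison, those with the largest estimate among the called loci, or the smallest p where none was called.

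Replicate numbers were checked for pairing. Within a strain, deviations of same-numbered libraries from their group means correlated between each pair of times, by 0.415 to 0.765 in WT and 0.555 to 0.748 in rneΔIDR, and without pSymA by 0.136 to 0.501 and 0.107 to 0.239. Same-numbered libraries of a strain were thus treated as 1 culture in the half-lives, the other values per culture and the fits with a culture block. The main per-locus tests had no block and took the libraries as independent. The correlations cannot tell a shared culture from shared handling. Fits with the culture as a block are printed where they changed a count by over 1.5 times. The scripts were tested on simulated counts with known changes, drawn from the real means and library sizes as independent libraries. In the slope comparison 0% of loci changed by 0.1 log2 units per min in either direction were recovered, 8% of those raised by 0.2 and 0% of those lowered by 0.2, and 1 of the 5 calls was an unchanged locus. At 0 min 3 of 55 calls were unchanged loci. No column of per-sample values was left unused (0). Counts per locus were low, with a median of 8 to 49 reads over the libraries, and floors of 3 counts and intervals cover counting error only, since reads of amplified libraries are not independent molecules. The 95% Wilson interval of the share of reads in genes was 22.7% to 22.8% in WT 0 min replicate 1 and 12.4% to 12.5% in WT 9 min replicate 2. Values were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots with Matplotlib 3.10.9.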

Results

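Decay of mRNA after a stop of transcription was measured in the nitrogen-fixing soil bacterium Sinorhizobium meliloti, strain Rm1021. The wild type (WT) was set beside a strain, rneΔIDR, whose RNase E lacks its intrinsically disordered region. RNase E is the endonuclease that starts the decay of many bacterial mRNAs, and its disordered part holds the other proteins of the degradosome. Rifampicin, which blocks the start of transcription by RNA polymerase, was added at 200 µg/mL, and RNA was sequenced from samples taken just before the drug (0 min) and 1, 3 and 9 min later. Each strain had 2 biological replicates at each of the 4 times, 8 groups and 16 libraries in all. The files covered 6234 loci, 3360 on the chromosome, 1290 on the megaplasmid pSymA and 1582 on the megaplasmid pSymB by the prefix of their locus tags. The libraries held 1524821 to 4769240 reads by their deposited totals, of which 242228 to 1016892 lay in genes.

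Relative to the library totals, protein-coding transcripts as a whole had fallen less by 9 min in rneΔIDR than in WT. The summed RPKM of all genes stood at 56.5% ± 0.282 (SD, n = 2) of its 0 min value after 9 min in WT and at 71.9% ± 5.33 in rneΔIDR. At 3 min it stood at 81.6% ± 2.91 in WT and 85.3% ± 6.12 in rneΔIDR, a difference smaller than the SD in rneΔIDR. The median RPKM over the 4171 tested loci stood at 9 min at 33.5% ± 0.676 of the median at 0 min in WT and at 54.0% ± 2.19 in rneΔIDR. Both rneΔIDR cultures lay above both WT cultures. At 3 min the median RPKM stood at 75.4% ± 4.19 in WT and 83.0% ± 1.60 in rneΔIDR. At 1 min the values were 94.4% ± 4.60 and 91.5% ± 8.04, a difference smaller than the spread between replicates. Reads in genes made up 22.0% ± 0.992 of the library in WT and 21.4% ± 0.419 in rneΔIDR before the drug, and 13.1% ± 0.949 and 16.5% ± 0.836 at 9 min. At 3 min they made up 19.5% ± 2.00 in WT and 19.6% ± 0.978 in rneΔIDR. These values assume that the reads outside genes, 77.3% to 87.6% of each library, came from RNA equally stable in both strains, which was not tested. An exact permutation test of 2 against 2 cultures cannot go below p = 0.333, and it gave p = 0.333 (two-sided) for the median RPKM at 9 min.

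**Figure D1:**
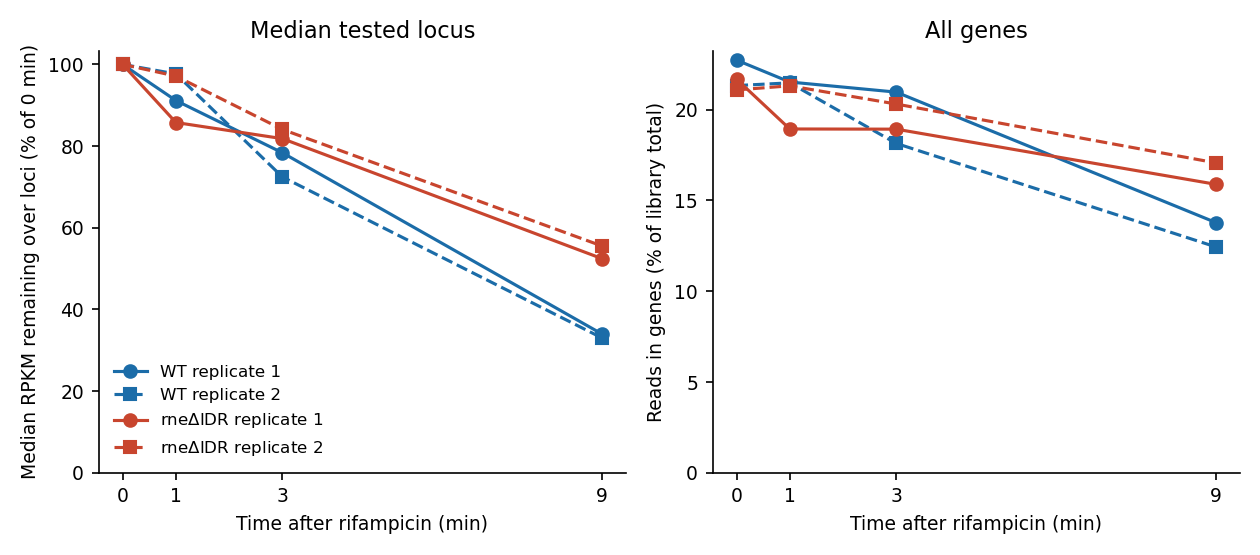
Median RPKM over the tested loci, in percent of the median at 0 min (left), and reads in genes as a percent of the library total (right), against the time after rifampicin in min. Each line is 1 culture of WT or rneΔIDR. At 9 min the median RPKM stood at 33.0% and 34.0% in the WT cultures and at 52.5% and 55.6% in the rneΔIDR cultures.

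The median half-life over loci was longer in both rneΔIDR cultures than in both WT cultures. Among loci with a falling RPKM, the median half-life was 5.49 min ± 0.217 (SD, n = 2 cultures) in WT and 8.52 min ± 0.420 in rneΔIDR, 1.55 times as long. The short-lived class shrank: 10.7% ± 0.797 of the tested loci had a half-life under 3 min in WT and 3.87% ± 1.102 in rneΔIDR. The RPKM fell with time at 85.5% ± 2.81 of the loci in WT and at 77.8% ± 0.0339 in rneΔIDR. Chromosomal transcripts had a median of 5.31 min ± 0.305 in WT and 8.59 min ± 0.275 in rneΔIDR. Transcripts of pSymB went from 6.19 min ± 0.0968 to 9.18 min ± 0.103, and those of pSymA from 5.77 min ± 0.446 to 7.21 min ± 1.08, the smallest change of the 3 replicons. The medians cover falling loci, whose share differed between the strains. From the median slope of all tested loci the half-lives were 6.40 and 11.8 min, 1.85 times as long. Centring each library on its median gave 10.98 and 13.1 min, a ratio of 1.19, and a pseudocount of 10 gave 9.30 and 13.6 min. Each of the strain differences on RPKM + 1 had an exact permutation p = 0.333 (two-sided), the smallest that 2 against 2 cultures allow. Half-lives are relative to the library totals that the authors divided by and rest on log2(RPKM + 1), which lengthens those of weakly expressed loci.

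The strains were compared at loci of different rates of fall. Loci that fell in 1 WT culture were ranked by their slope there and split into 5 groups of equal size, and the other WT culture gave the WT value. In the fastest group the median slope was -0.32 log2 units per min in WT and -0.22 in rneΔIDR, and in the slowest -0.06 and -0.02, so the difference in slope was larger where transcripts fell fast. In the fastest group the median slope corresponded to a half-life of 3.13 min in WT and 4.64 min in rneΔIDR, a ratio of slopes of 0.675. In the slowest group the half-lives were 18.1 and 73.2 min, a ratio of 0.252. The 3 groups between had ratios of 0.590, 0.556 and 0.487. The ratio depends on the zero that the library totals set, most of all where slopes are near 0. These are means of both choices of the ranking culture. In the slowest group the half-lives depended on that choice, with 13.1 and 49.1 min when WT replicate 1 was ranked and 23.1 and 97.4 min when replicate 2 was.

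**Figure D2:**
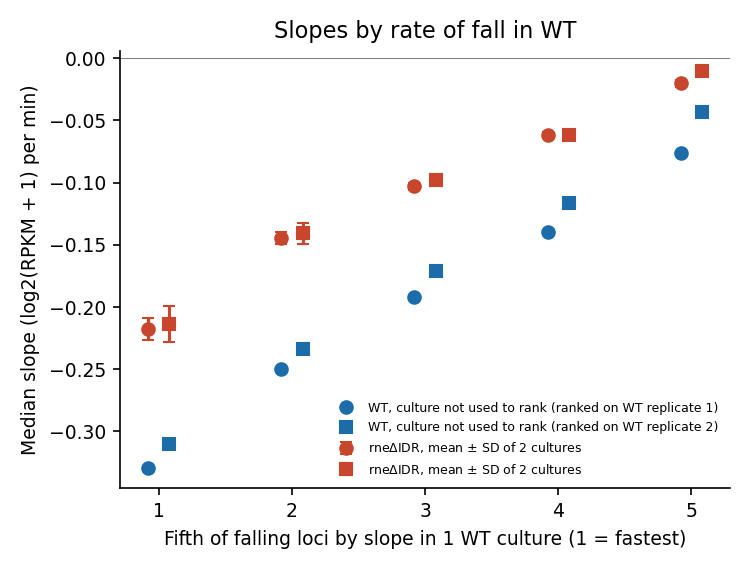
Median slope of log2(RPKM + 1) per min in 5 equal groups of loci, ranked from the fastest to the slowest fall in 1 WT culture. WT values come from the culture not used to rank, and rneΔIDR values are mean ± SD of 2 cultures. The median slope was -0.32 in WT and -0.22 in rneΔIDR in the fastest group, and -0.06 and -0.02 in the slowest.

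In WT, 1844 of the 4171 loci fell and 489 rose relative to all gene reads after rifampicin, by edgeR's quasi-likelihood test of the slope over the 4 times at a Benjamini-Hochberg adjusted threshold of 0.05. In rneΔIDR 1173 fell and 408 rose. On the scale of the deposited library totals, which keeps the loss of gene reads as a whole, 2743 fell and 176 rose in WT, and 1648 fell and 220 rose in rneΔIDR. On that scale the median slope was -0.17 log2 units per min in WT and -0.09 in rneΔIDR, against -0.09 and -0.05 relative to gene reads. Of the loci called in both strains on library totals, 1755 of 1756 had the same sign. They comprised 1614 loci that fell in both, where independent lists would share 1083.78, and 141 that rose in both, where such lists would share 9.28. Across loci, which are not independent replicates, the slopes of the strains had a Pearson correlation of 0.784. TMM and DESeq2 size factors, which assume that most loci keep their level, turned the balance to 1036 rising and 958 falling and to 1047 and 952 in WT, and to 742 and 686 and to 751 and 681 in rneΔIDR. Centring each library on its median gave 1027 rising and 904 falling in WT, and 762 and 589 in rneΔIDR. Leaving out a whole rneΔIDR culture brought the rneΔIDR count of 1581 to 633 (without replicate 1) or 563 (without replicate 2).

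The fastest losses in WT were those of SMa1749 (on pSymA) and SM_b22018 (on pSymB). SMa1749 went from an RPKM of 28.0 ± 1.02 (SD, n = 2) at 0 min to 6.79 ± 1.64 at 3 min. At 9 min it had 0 reads in both WT libraries, at least 21.4-fold and 24.9-fold lower than at 0 min against a floor of 3 counts per library. In rneΔIDR it still had 4 and 3 reads at 9 min, an RPKM of 2.17 ± 1.06. SM_b22018 went from 93.3 ± 14.8 to 6.87 ± 0.462 at 3 min and to 0 reads at 9 min in WT, at least 22.5-fold and 19.9-fold lower. Its rneΔIDR libraries had 1 read each at 9 min. The largest rises relative to gene reads were those of SMa1185 and SM_b20061. SM_b20061 rose by 0.61 ± 0.09 log2 units per min (SE; edgeR adjusted p = 0.000177), from 0 and 5 reads at 0 min to 13 and 15 at 9 min. SMa1185 (slope 0.62 ± 0.24, SE; edgeR adjusted p = 0.0491) rested on WT 9 min replicate 2, which had 662 reads where replicate 1 had 7. Without that library its slope was -0.04. On library totals its adjusted p by edgeR was 0.0579.

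The strain difference in slope was tested directly at each locus. It was called at 38 loci, 37 with a higher (less negative) slope in rneΔIDR and 1 with a lower one (edgeR quasi-likelihood test, rneΔIDR slope minus WT slope). All 37 fell in WT. In rneΔIDR 15 of them fell, 3 rose and 19 had no call. On library totals the median slope of the 37 corresponded to a half-life of 3.20 min in WT and 12.7 min in rneΔIDR. The 37 were selected by this difference in the same libraries, so these half-lives are likely to overstate its size. Among the 37, SMc02151 had the largest difference, 0.41 ± 0.07 log2 units per min (SE; edgeR adjusted p = 0.0343). Its RPKM went from 48.7 ± 11.7 (SD, n = 2) to 1.09 ± 0.0762 over 9 min in WT and from 42.7 ± 1.73 to 16.5 ± 3.82 in rneΔIDR, half-lives of 1.65 and 6.50 min on library totals. SMc02875 followed with 0.37 ± 0.07 (SE; edgeR adjusted p = 0.0414), from an RPKM of 13.3 ± 0.969 to 0.995 ± 0.799 in WT and from 11.1 ± 0.125 to 11.99 ± 4.02 in rneΔIDR. SMc01928 was the locus with the lower slope in rneΔIDR, -0.10 ± 0.02 (SE; edgeR adjusted p = 0.0414). It rose in both strains, from 160.4 ± 13.8 to 570.3 ± 134 in WT and from 235 ± 7.50 to 602 ± 44.9 in rneΔIDR. On library totals its difference did not pass (edgeR adjusted p = 0.240). SMa1749, with 0 reads at 9 min in WT, had a larger estimate than SMc02151 but was not called, 0.67 ± 0.12 (SE; edgeR adjusted p = 0.0710). On library totals SMa1749 passed, with 0.65 ± 0.11 (SE; edgeR adjusted p = 0.0247).

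The count of 38 loci moved with the scale and with the libraries used. On library totals 308 loci differed, 307 of them with the higher slope in rneΔIDR and 37 of them shared with the 38. TMM and DESeq2 size factors each called 43, 15 with the higher and 28 with the lower slope in rneΔIDR, and centring on library medians called 6, 5 higher and 1 lower. Same-numbered libraries of a strain shared deviations. With that culture as a replicate block 245 loci were called (195 higher, 50 lower), the 38 among them, and 897 on library totals (888 higher, 9 lower). Estimates above 0 were found at 64.6% of all tested loci relative to gene reads and at 83.1% on library totals. Without 1 library the count lay between 4 (without WT 9 min replicate 2) and 121 (without WT 1 min replicate 2), with 45 without WT 1 min replicate 1, 31 without rneΔIDR 9 min replicate 1 and 6 to 19 without any one of the other 12. Without 1 culture it was 0 to 3.

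**Figure D3:**
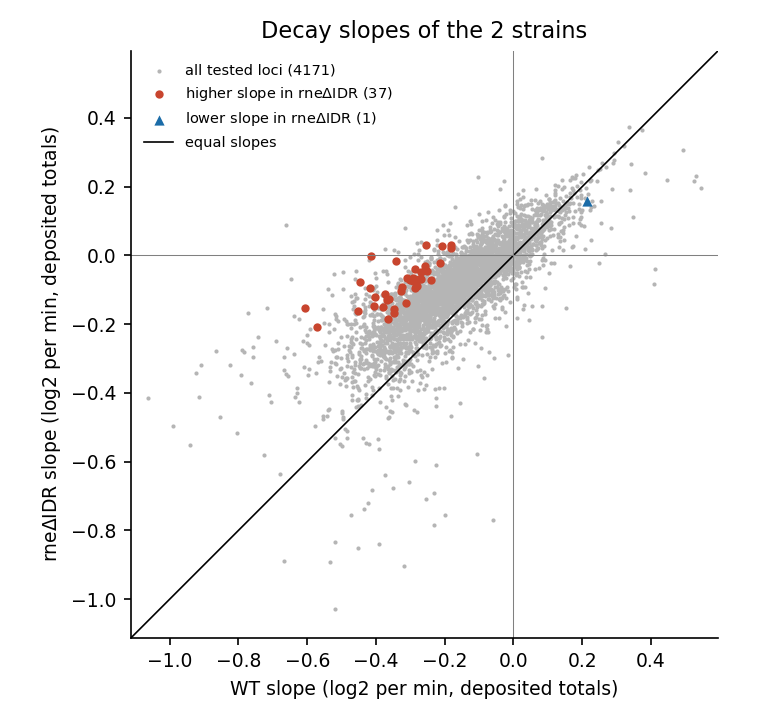
Decay slope of each of the 4171 tested loci in WT (horizontal) and rneΔIDR (vertical), in log2 units per min on library totals. Coloured symbols mark the 37 loci with a higher and the 1 with a lower slope in rneΔIDR relative to gene reads, and the line marks equal slopes. The rneΔIDR slope lay above the WT slope at 83.1% of the loci.

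**Figure D4:**
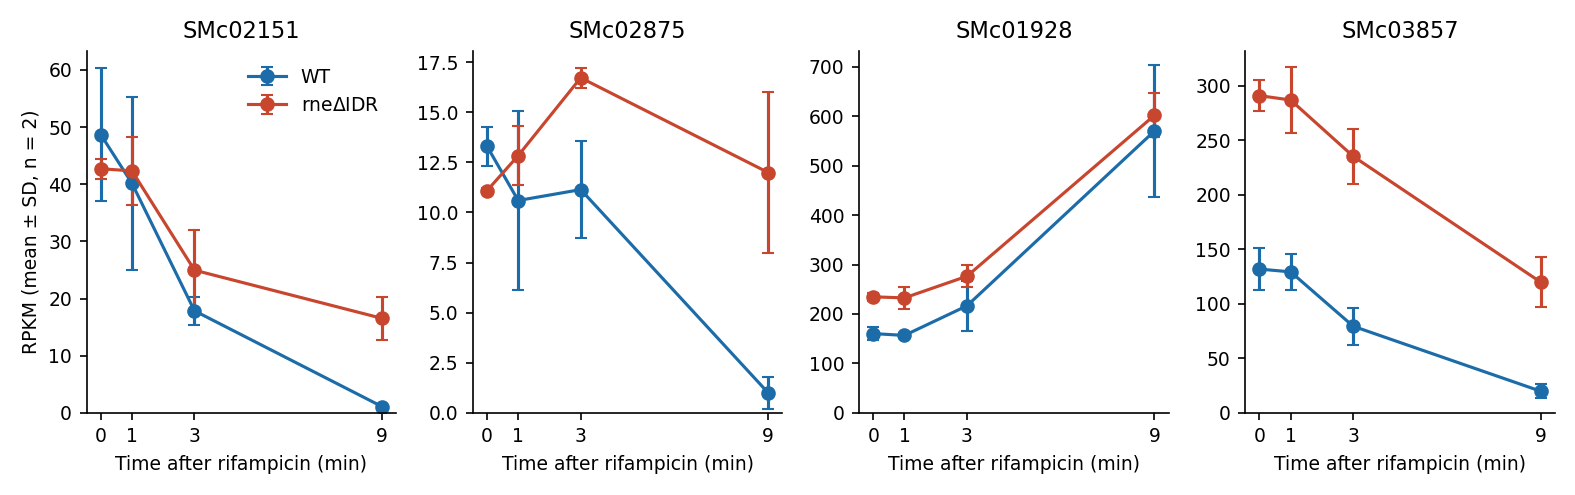
RPKM of SMc02151, SMc02875, SMc01928 and SMc03857 against the time after rifampicin in min, as mean ± SD of 2 replicates in WT and rneΔIDR. At 9 min SMc02151 stood at 1.09 in WT and 16.5 in rneΔIDR, and SMc01928 at 570.3 and 602.

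Called loci were counted on each replicon, and no test compared the shares between replicons. Relative to gene reads, 1423 of 2846 chromosomal loci fell in WT and 350 rose. On pSymA 151 of 533 fell (28.3%) and 41 rose, and on pSymB 269 of 791 fell (34.0%) and 98 rose. In rneΔIDR 922 chromosomal loci fell (32.4%), 100 on pSymA (18.8%) and 151 on pSymB (19.1%). On library totals 2047 chromosomal loci fell in WT and 132 rose, 250 and 7 on pSymA, and 445 and 37 on pSymB. In rneΔIDR 1260, 142 and 245 fell on that scale. The median WT slope on library totals was -0.18 log2 units per min on the chromosome, -0.16 on pSymA and -0.15 on pSymB. The shares of called loci thus do not measure how fast transcripts of a replicon fell. As a set tested against the other loci by camera with a preset correlation of 0.01, chromosomal loci had lower slopes in WT relative to gene reads (adjusted p = 0.0422). That call did not hold with the correlation between loci estimated from the data (adjusted p = 0.351 with an estimated correlation). For the strain difference in slope the chromosome stood above the other loci (camera adjusted p = 0.00205), with 34 members called higher and 1 lower, 56 and 5 when adjusted over the list alone. That call did not hold with an estimated correlation (camera adjusted p = 0.182) or with libraries centred on their median (0.106). The pSymA loci stood below the others (camera adjusted p = 0.00205) with 0 called by edgeR, 0 also when adjusted over the list alone. This call was likewise lost in the same settings, with camera adjusted p = 0.182 with an estimated correlation and 0.106 with centred libraries. Other settings kept both lists past the threshold. On library totals camera gave adjusted p = 1.46e-05 for the chromosome and 9.27e-07 for pSymA. With the culture as a replicate block camera gave 0.00157 and 0.000943. The median difference on pSymA was -0.01 log2 units per min relative to gene reads and 0.04 on library totals. On library totals edgeR called 11 pSymA loci higher and 0 lower, against 254 and 0 on the chromosome and 42 and 1 on pSymB. The pSymB loci stood below the others but did not pass relative to gene reads (camera adjusted p = 0.0566). Of them 3 were called higher, and 1 when adjusted over the list alone. The pSymB list passed on library totals (camera adjusted p = 0.0245). It did not pass with an estimated correlation (camera adjusted p = 0.182) or with centred libraries (0.143). In rneΔIDR no replicon list passed for the slope, with camera adjusted p = 0.380 for the chromosome and pSymB and 0.759 for pSymA.

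More loci were called at 9 min than at 3 min, and the changes were also larger at 9 min. On library totals the median change in WT was -0.30 log2 units at 3 min (median SE 0.37) and -1.53 at 9 min (0.39). The counts therefore do not show when the changes began. Relative to gene reads, WT had 0 loci called at 1 min against 0 min (edgeR, 220 at an unadjusted p below 0.05, 1 by DESeq2). It had 331 at 3 min (61 higher, 270 lower) and 2155 at 9 min (412 higher, 1743 lower). The rneΔIDR strain had 0 at 1 min (edgeR, 71 at an unadjusted p below 0.05, 0 by DESeq2), 81 at 3 min (10 higher, 71 lower) and 1403 at 9 min (341 higher, 1062 lower). On library totals the 3 min counts were 334 (6 higher, 328 lower) and 70 (4 higher, 66 lower), and the 9 min counts 2793 (154 higher, 2639 lower) and 1732 (180 higher, 1552 lower). With the culture as a replicate block 4 loci (1 higher, 3 lower) were called in WT at 1 min and 0 in rneΔIDR. The 3 min counts rose with that block to 925 (339 higher, 586 lower) in WT and 344 (104 higher, 240 lower) in rneΔIDR. TMM made the balance at 9 min 929 higher and 899 lower in WT, and 633 and 629 in rneΔIDR. At 3 min TMM gave 226 higher and 203 lower in WT and 47 and 62 in rneΔIDR. WT 1 min replicate 1 stood apart from the other libraries, with 1469 loci at 0 reads where the other 1 min libraries had 195 to 342. Without WT 1 min replicate 2, which leaves that library alone at 1 min, 395 loci were called in WT at 1 min and 175 for the strain difference. The 3 min count in WT without 1 library lay between 30 (without WT 3 min replicate 2) and 509 (without WT 1 min replicate 1).

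Single-locus differences between the strains in the change from 0 min were called at 9 min and not at 1 or 3 min. On library totals the median difference was 0.09 log2 units at 3 min (median SE 0.52) and 0.64 at 9 min (0.55). The lack of calls at 3 min therefore does not show equal changes in the strains. The change from 0 min differed between them at 0 loci at 1 min (edgeR, 62 at an unadjusted p below 0.05, 0 by DESeq2), at 0 loci at 3 min (60 and 0) and at 13 loci at 9 min, all 13 less reduced or more raised in rneΔIDR. On library totals 17 loci differed at 9 min, with the culture as a replicate block 119 (95 higher, 24 lower), and with both 561 (556 higher, 5 lower). TMM left 6 (4 higher, 2 lower). The 9 min count was 2 without any one of the 4 libraries at 0 min or without WT 9 min replicate 1, 3 without rneΔIDR 9 min replicate 2, 4 without WT 9 min replicate 2, and 8 without either WT library at 3 min or either rneΔIDR library at 1 min. Without any one culture it was 0.

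Before rifampicin no single locus passed the main test between the strains, and other fits called some. edgeR called 0 of the 4171 loci between rneΔIDR and WT at 0 min, where 358 had an unadjusted p below 0.05 and the smallest adjusted p was 0.0578. The loci with the smallest p were SMc03857 and SMc02983, with more reads in rneΔIDR, and SMc04332 and SMc00870, with fewer. SMc03857 had an RPKM of 291 ± 14.2 (SD, n = 2) in rneΔIDR and 132 ± 19.5 in WT, a log2 difference of 1.19 ± 0.19 (SE). SMc02983 had 211 ± 14.3 and 116 ± 5.53, a log2 difference of 0.91 ± 0.15. SMc04332 had 125 ± 27.2 in rneΔIDR and 340.4 ± 34.7 in WT (-1.41 ± 0.21), and SMc00870 had 896 ± 26.5 and 1892 ± 359.9 (-1.03 ± 0.17). Their adjusted p by edgeR was 0.0578 each. DESeq2 called 40 loci (16 higher, 24 lower in rneΔIDR), and edgeR on loci with a mean RPKM of 50 or more called 11 (2 higher, 9 lower). With a block that crosses the replicate numbers between the strains, edgeR called 88 (53 higher, 35 lower), and without WT replicate 1 it called 35 (8 higher, 27 lower). In simulated data with the depth and spread of these libraries, 44% and 48% of loci raised or lowered 4-fold were recovered in this comparison, and 2% and 10% of those changed 2-fold, so that most 2-fold differences would be missed at this depth. No replicon list passed (camera adjusted p = 0.513 for the chromosome, 0.206 for pSymA and 0.137 for pSymB). By edgeR 0 of their members were called, and 2 higher and 5 lower chromosomal loci when adjusted over the list alone.

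**Figure D5:**
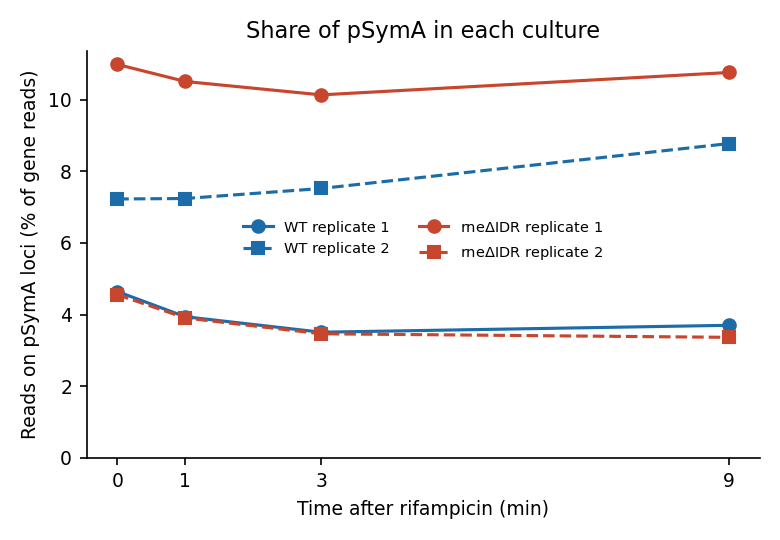
Share of gene reads on pSymA loci, in percent, against the time after rifampicin in min, 1 line per culture. At 0 min the share was 4.64% and 7.23% in the WT cultures (replicates 1 and 2) and 10.98% and 4.56% in the rneΔIDR cultures.

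The share of pSymA transcripts varied between cultures of one strain more than between the strain means. They took 4.64% of the gene reads in WT replicate 1 and 7.23% in replicate 2 at 0 min, and 10.98% and 4.56% in rneΔIDR. At every time, 92 of the 533 tested pSymA loci were over 2-fold higher in WT replicate 2 than in replicate 1, and 115 were over 2-fold lower in rneΔIDR replicate 2 than in replicate 1. The corresponding numbers among 2846 chromosomal loci were 12 and 3. Comparisons of pSymA loci between the strains carry this spread between cultures.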

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

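The test on library totals over other groupings of the libraries, the test of a shift of every locus by the library scale, and the counts on library totals were chosen only after the result was seen.

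A difference between the strains in the same time course marked 7 results. Relative to gene reads, the decay slope differed at 38 loci and the change to 9 min at 13. On library totals the numbers were 308 and 17. Among the loci called relative to gene reads, SMc02151 (0.41 log2 units per min) and SMc02875 (0.37) had the largest differences, and SMc01928 (-0.10) was the 1 locus with a lower slope in rneΔIDR. Each rests on a test of the difference itself by edgeR. SMc02151 was called in 19 of 40 alternatives, SMc02875 in 10 of 40 and SMc01928 in 9 of 41, with the same sign in all of them.

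Splits of the strain labels within each time do not exclude chance for these counts. Of 100 splits drawn from 648, the real one included, 9 called as many loci as the real 38, with 569 as the highest other. On library totals 10 did, with a real count of 308 and 636 as the highest other. A split that calls many times the real count points to a structure of the samples, and the 3 splits relative to gene reads with the most calls (569, 412 and 243) kept 0 cultures whole. The 3 groupings that keep the 4 cultures whole are too few for a share under 0.05, with 38 for the real grouping (1 with as many) and 1 as the highest other. For the slopes within a strain, the fit used the libraries of that strain alone. Of 100 drawn splits of the times, the real one (1) alone reached its count. This was 2116 in WT against 1777 as the highest other, and 1632 in rneΔIDR against 1172. The splits moved the libraries of a culture as if independent, so they make chance unlikely without excluding it.

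Thinning all libraries to equal gene reads keeps the expected share of each locus, so it tests only for a bias of the estimates at low counts. Calls dropped to 88 on library totals and to 5 relative to gene reads. Such a bias at lower depth does not account for the shallower slopes of rneΔIDR, since the median slope difference on library totals after thinning was 0.973 of that before. Nor does WT 1 min replicate 1, without which it was 0.985 of its value (244 calls). A constant background of reads in rneΔIDR would shrink the difference at strongly expressed loci. From the weakest to the strongest of 5 groups the difference ran 0.0565, 0.0654, 0.0806, 0.0822 and 0.0663. It was 1.17 times as large in the strongest as in the weakest. The added 1 RPKM flattens the slopes of the weakest group in both strains, so this ratio cannot exclude a background. The difference remained in the strongest group, with a mean RPKM of 61.3 or more. A shift of every locus by the library scale would leave the span of slopes between the fastest and slowest loci alike, and that span in rneΔIDR was 0.707 to 0.796 of that in WT, and 1.13 to 1.24 the other way round. Slower decay with the RNase E deletion is thus 1 open explanation, with 2 cultures per strain, a total dominated by reads outside genes whose stability is unknown, and the action of rifampicin in either strain untested.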

How the results depend on the processing

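The counts on library totals, the fits that add the culture to them, the crossed block, limma on log2(RPKM + 1), thinning, the half-life over all loci and the sum of read counts were chosen only after the result was seen. Falling loci outnumbered rising ones for the slope of each strain in all alternatives run but TMM, DESeq2 size factors and centring, and the ratio of half-lives stayed above 1 in all alternatives. Depth limits the per-locus strain difference, with a median of 8 reads per locus in the shallowest library. Leaving out a library leaves a group with 1 sample, assumed to vary like the other groups. Scaling to stable RNAs and tests of lists by gene name were not run, since no tag carries a name. For the values below the cause was not tested, except that fewer loci were tested at a mean RPKM of 50 or more, and that TMM, DESeq2 size factors and centring remove a fall shared by most loci. Counts are of called loci, "9 min difference" is the strain difference in the change to 9 min, and lists are given with adjusted p.

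With limma at a pseudocount of 0.1, the slope difference had 405 calls, the 9 min difference 71, and lists 0.000366 (pSymA, WT slope), 0.0213 (pSymB, WT slope) and 0.0124 (pSymB, slope difference). At a pseudocount of 10, calls were 2 for WT at 1 min, 536 for WT at 3 min, 220 for rneΔIDR at 3 min and 7 for the 9 min difference. The half-lives were 5.01 and 8.02 min (WT and rneΔIDR) at 0.1 and 9.30 and 13.6 min at 10. Without a filter, slope difference 15, WT at 3 min 220, WT half-life 6.29 min, ratio 1.40. At a mean RPKM of 50 or more, 0 min 11, WT slope 697, rneΔIDR slope 580, slope difference 66, WT at 3 min 218, WT at 9 min 652, rneΔIDR at 9 min 526, 9 min difference 23, half-lives 5.86 and 9.70 min, ratio 1.66. Centred on library medians, slope difference 6, rneΔIDR at 3 min 50, 9 min difference 2, half-lives 10.98 and 13.1 min, ratio 1.19, and lists 0.407 (chromosome, WT slope) and 0.106 (chromosome and pSymA, slope difference, 0.106 each). Without a trend on mean expression, slope difference 13. With TMM, 0 min 3 and 9 min difference 6, and with DESeq2 size factors 3 and 6. With the groups of the comparison alone, rneΔIDR at 3 min 0 and 9 min difference 0 by edgeR. Over 0, 1 and 3 min, WT slope 387, rneΔIDR slope 88, slope difference 0, half-lives 4.93 and 5.85 min, ratio 1.19. Over 1, 3 and 9 min, slope difference 2 and WT half-life 5.14 min. As a line on single libraries, slope difference 15. Over all loci, half-lives 6.40 and 11.8 min, ratio 1.85. As read counts, 59.5% of gene reads remained at 9 min in WT.

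With the culture as a replicate block, slope difference 245, WT at 1 min 4, WT at 3 min 925, rneΔIDR at 3 min 344, 9 min difference 119, list 0.0929 (chromosome, WT slope), and it moved no other call across the threshold and no other count by over 1.5 times. With library totals as well, slope difference 897, WT at 1 min 2, WT at 3 min 900, rneΔIDR at 3 min 351, rneΔIDR at 9 min 2218, 9 min difference 561. With a crossed block of WT replicate 1 with rneΔIDR replicate 2 and the reverse, 0 min 88, slope difference 152, WT at 1 min 1, WT at 3 min 768, rneΔIDR at 3 min 245, 9 min difference 60. With DESeq2, 0 min 40, slope difference 93, WT at 1 min 1, 9 min difference 39. With limma on log2(RPKM + 1), slope difference 305 and 9 min difference 34. On library totals, slope difference 308, and lists 0.000828 (pSymA, WT slope), 0.0198 (pSymB, WT slope) and 0.0245 (pSymB, slope difference). Thinned, slope difference 5, and 88 on library totals. With an estimated correlation, lists 0.351 (chromosome, WT slope) and 0.182 (chromosome and pSymA, slope difference, 0.182 each). With fry, which tests a list against no change and not against other loci, the direction turned for pSymA and pSymB in WT (0.00821 and 0.000157), pSymA and pSymB in rneΔIDR (0.0159 and 0.00220) pSymA and pSymB in the slope difference (0.806 and 0.158) and the chromosome at 0 min (0.785), and the chromosome in rneΔIDR passed (0.000617).

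Without any one library or culture, counts ranged over 0 to 35 at 0 min, 1731 to 2466 for the WT slope, 563 to 1774 for the rneΔIDR slope and 0 to 121 for the slope difference. For WT they were 0 to 395 at 1 min, 0 to 509 at 3 min and 1488 to 2385 at 9 min, for rneΔIDR 0 to 0, 0 to 122 and 468 to 1612, and for the difference 0 to 175, 0 to 0 and 0 to 13, all by edgeR. On library totals without WT 1 min replicate 1 they were 3034 for the WT slope, 2039 for the rneΔIDR slope, 244 for the slope difference, 497 for WT at 3 min, 2935 for WT and 1924 for rneΔIDR at 9 min and 20 for the 9 min difference. Half-lives were 5.33 to 5.64 min in WT and 8.22 to 8.81 min in rneΔIDR, with a ratio of 1.50 to 1.61, and RPKM remaining at 9 min was 56.3% to 56.7% and 68.1% to 75.7%. The slope of SMa1185 in WT ranged from -0.0380 (without WT 9 min replicate 2) to 0.73 (without WT 9 min replicate 1).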

Other observations

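The tests of reads per molecule, of loss within 1 min and of depth in the library with many loci at 0, and the description of the pSymA set, were chosen only after the result was seen.

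A set of 89 pSymA loci was switched between cultures. They were over 2-fold higher in WT replicate 2 than in replicate 1 and over 2-fold lower in rneΔIDR replicate 2 than in replicate 1 at every time, where 19.8 would meet both conditions if these were independent. Their summed RPKM at 0 min was 335 and 7190 in the WT cultures (replicates 1 and 2) and 15933 and 527 in the rneΔIDR cultures, and at 9 min 118 and 5334, and 10141 and 418. Of the 89, 80 lay next to another member, where 1000 drawn sets of pSymA loci gave 4 to 36. The loci were selected by this pattern, and they carry no gene names here.

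The RPKM of short genes fell faster than that of long ones, with weak correlations across loci, and the cause was not tested. Across 5 equal groups from the shortest to the longest coding length, the half-life from the median slope was 5.26, 5.65, 6.23, 7.10 and 7.38 min in WT and 8.23, 9.12, 11.2, 15.3 and 17.2 min in rneΔIDR. The Spearman correlation of length with slope across loci was 0.152 and 0.161 in the WT cultures and 0.204 and 0.195 in the rneΔIDR cultures.

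Many loci had 0 reads in WT 1 min replicate 1, 1469 where the other 1 min libraries had 195 to 342. Lower depth does not account for it, since the library had 1.04 times the mean gene reads of the other 3. Nor does loss within 1 min of rifampicin, since the 461 of these loci with 10 or more reads at 0 min retained a median of 52.4% of their RPKM at 3 min in the same culture. Few molecules amplified many times could account for it: the loci at 0 implied at least 9.87 reads per molecule at each expected count, against at most 1.82 in the other 1 min libraries, and at 2 to 4 expected reads the median count above 0 was 3.64 times that expected.

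Replicate numbers ran against each other between the strains. Deviations from the group mean correlated at -0.694 to -0.335 between same-numbered libraries of WT and rneΔIDR. Without pSymA the correlations were -0.164 to -0.0203, so whether pSymA transcripts alone may produce the pattern cannot be told. For the slope difference the other groupings of the 4 cultures called at most 1 locus and the labelled one 38, which speaks against an exchange of strain labels between 2 cultures. At 0 min the values went the other way, with 78 loci called when WT replicate 1 was grouped with rneΔIDR replicate 2 and 0 in the labelled grouping. What the cultures shared remains open.

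Hypotheses on the slopes were tested. On the scale of slope differences, longer coding sequences being slowed more was not borne out, with Spearman correlations of length and slope difference of 4.32e-05 to 0.0603 across loci in the 4 pairs of cultures. The difference of the median slopes went from 0.0686 in the shortest to 0.0774 in the longest of the 5 groups, and the ratio of the half-lives given above rose with length, which was not tested. For slowing in proportion to the WT rate, the ratio of slopes differed by 0.451 and 0.394 between the fastest and the slowest of 5 groups, but that ratio depends on the zero set by the library totals. The span of slopes, which does not, was 0.707 to 0.796 of that in WT, so proportional slowing together with a shift of scale stays open. Neighbouring loci fell together: WT slopes of 3463 adjacent pairs correlated at 0.449, above the highest of 1000 shuffled orders (0.0546), and the slope difference at 0.180 (0.0653).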
